A study of Triticum aestivum with 161 samples.

How the data were processed

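Total RNA from caryopses was hybridised to Affymetrix wheat arrays, 1 array per plot and 161 in all, and each array was assigned to its group by the cultivar, nitrogen supply, site and season that its labels give. The deposited values are log2 signals per probe set, made by the authors with RMA (background correction, quantile normalization and a median-polish summary), which the submitters' processing notes name; its version and software, and whether all arrays were processed together, are not given in the sources used here. The values ranged from 1.59 to 15.06. Their distributions fell into a set per season, with a 1st percentile of 2.29 to 2.36 in 2009, 2.12 to 2.19 in 2010 and 2.57 to 2.61 in 2011, as if each season had been normalized on its own. Differences between seasons are therefore given relative to the median of all probe sets, whereas nitrogen, cultivar and site contrasts lie within seasons. Raw array files were not used here, and signals of single probes and the background of each array were not analysed here.

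All 161 arrays were used. Of 61288 probe sets, 110 Affymetrix controls were left out and 61178 were tested. The annotation gave 1 gene to 1273 probe sets (771 genes, 770 of them matched to a RefSeq entry) and none to 59905. A symbol or synonym that names a protein was found for 102 genes with 200 probe sets, and gene names in the text rest on these. No genome build was given for this series, so positions are not stated.

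limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8) fitted a mean to each of the 54 groups, which left 107 residual degrees of freedom, and tested contrasts with moderated statistics (two-sided), with equal weight for each group of a side. Nitrogen contrasts averaged over cultivars at Rothamsted in 2009 and 2010, cultivar contrasts set each cultivar against the mean of the others over the environments at N200, season contrasts used Rothamsted (all nitrogen levels for 2010 against 2009, N200 where 2011 is compared), and site contrasts set RAGT against Rothamsted within a season. Differences of the nitrogen effect between seasons and cultivars and of the site effect between years were tested as interactions, with F tests where several cultivars were compared. P-values were adjusted by the method of Benjamini and Hochberg over the 61178 probe sets of each contrast, and a probe set was called at an adjusted p under 0.05. Each p-value therefore rests on the spread between plots within groups, pooled per probe set over all 54 groups. Shares of variance came from sums of squares per probe set, taken in order, over probe sets with a mean of at least 6.

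Named genes followed a rule set before the data were examined. A gene was eligible when a probe set was called, had a mean of at least 6 on the higher side, belonged to 1 gene with an informative name and had the same sign in every stratum, which are the combinations of cultivar and season for nitrogen and site, the cultivars for seasons and the environments for a cultivar. The largest changes in each direction were named, up to 10 for N350 against N100, 4 for a season contrast, 6 for the sites (past the threshold in both years) and 3 for a cultivar. For interactions and the test over cultivars, the 3 named genes with the smallest p were taken. Of each fixed list, the largest called members were added or, where none was called, the member with the highest mean, and at most a pair of probe sets without a gene name per direction. For N350 against N100, 11 genes were eligible among rises and 8 among falls.

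Before the data were examined, 24 gene lists that fit wheat grain were fixed as patterns of gene names, and 6 of them had at least 5 probe sets: alpha gliadins, amylase and protease inhibitors, defence proteins, photosynthesis, LEA and ABA-related genes, and histones. Each was tested against all other probe sets with camera at its preset correlation of 0.01, with its adjusted p taken over the lists of a contrast, then with an estimated correlation. fry tested whether a list moved on its own, without a comparison with other probe sets. Members were also adjusted over the list alone.

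Other settings, named before the data were examined, were a block for the replicate number (15 blocks), only the arrays compared, probe sets with a mean of at least 6, quantile normalization of all arrays again, centred array medians, an intensity trend with robust hyperparameters, array weights, a fold minimum of 1.5, a covariate for the 3' minus 5' difference of control transcripts, each replicate, cultivar or environment left out, and single seasons. Leaving out the arrays far from their group mean and a set of lists assigned by name to every named gene were added after seeing the data. The arrays were also regrouped at random within strata, with 100 splits per result including the real one.

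The methods were tested on simulated data drawn with the group means and residual SDs of the real arrays, to which known changes were added. In N350 against N100, 74.6% of changes of 0.2 on the log2 scale and 100% of those of 0.5 and 1 were recovered with 12 false calls; in Hereward against the others the shares were 56.7%, 100% and 100% with 14 false calls, and in RAGT against Rothamsted in 2010 they were 32.8%, 98.5% and 100% with 9. The F test recovered 192 of 200 changes with 9 false calls, and camera recovered the changed list in 10 of 10 draws with 2 false calls in 50 tests of unchanged lists. The simulated noise was independent between probe sets, whereas the estimated correlations of the real lists ran from 0.0926 to 0.83. These draws therefore do not measure the false calls of camera at its preset correlation in the real data. Labels were checked with the 300 probe sets that differed most between cultivars on these arrays, and 161 of 161 arrays were closest to their own cultivar (lowest correlation with it 0.8, highest with another 0.289), a match that the choice of probe sets by these labels favours. The highest correlation between any pair of arrays was 0.997456, so no array was a copy of another. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. The depth of an array has no counterpart in read counts, and the number of arrays limits the precision.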

Results

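Transcript levels were measured in developing wheat grain (caryopses) taken 21 days after anthesis, during grain filling, from 6 cultivars grown in field plots. The 161 arrays fell into 54 groups of cultivar, nitrogen supply, site and season, 53 of them with 3 arrays and 1 with 2. Rothamsted was sampled in 2009 (53 arrays) and 2010 (54 arrays) at 100, 200 and 350 kg of nitrogen per ha, here N100, N200 and N350, and in 2011 (18 arrays) at N200. RAGT, a second site, was sampled at N200 in 2010 and 2011, with 18 arrays each. Each array gave a log2 signal for 61288 probe sets, between 1.59 and 15.06, and 24406 of them (39.9%) had a mean of at least 6. The number of arrays limits the precision of every value: the median SD between arrays of a group was 0.170. The p-values rest on the spread between plots of a group, which the labels call biological replicates, pooled over the 54 groups. That spread was unequal. Over probe sets with a mean of at least 6, the root mean square deviation of an array from its group mean ran from 0.07 to 0.34. A p-value therefore does not measure the spread of the compared groups alone. A gene could be named for 1273 probe sets, and 102 genes carried an informative symbol, so most changed probe sets remain without a name. Among probe sets with a mean of at least 6, environment (site and season) took a median of 52.5% of the variance of the 89 arrays at N200, cultivar 9.15% and their interaction 11.1%. At Rothamsted in 2009 and 2010 (107 arrays) nitrogen took a median of 2.33%, cultivar 15.5% and season 8.96%; over all probe sets the season share was 17.6% and the cultivar share 8.93%, and at N200 the cultivar share was 6.06%. The nitrogen share was 3.62% without replicate 1. These shares are of the values as deposited, so those of environment and season include any separate normalization of the seasons.

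The comparison of N350 with N100 asked which grain transcripts follow nitrogen supply. Serpins, inhibitors of serine proteases that accumulate in the endosperm, rose most among the named genes. WSZ1c rose by 1.40 on the log2 scale (SE 0.08, adjusted p = 1.58e-31), from a mean of 9.62 at N100 to 11.02 at N350 with 36 arrays each, which is 2.65-fold. WSZ2a rose by 1.15 (SE 0.08), WSZ2b by 0.88 (SE 0.06) and WSZ1b by 0.30 (SE 0.03). GAG56D, a gamma gliadin of the gluten storage proteins, rose from 13.12 to 13.56 (0.44, SE 0.03, adjusted p = 2.84e-25). The avenin-like storage proteins went the other way: ALP fell from 13.54 to 12.95 (-0.59, SE 0.06, adjusted p = 4.74e-13) and avnla by -0.36 (SE 0.04, adjusted p = 1.17e-11). Each of these genes moved in the same direction in 12 of 12 combinations of cultivar and season, which the rule for named genes required.

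**Figure D1:**
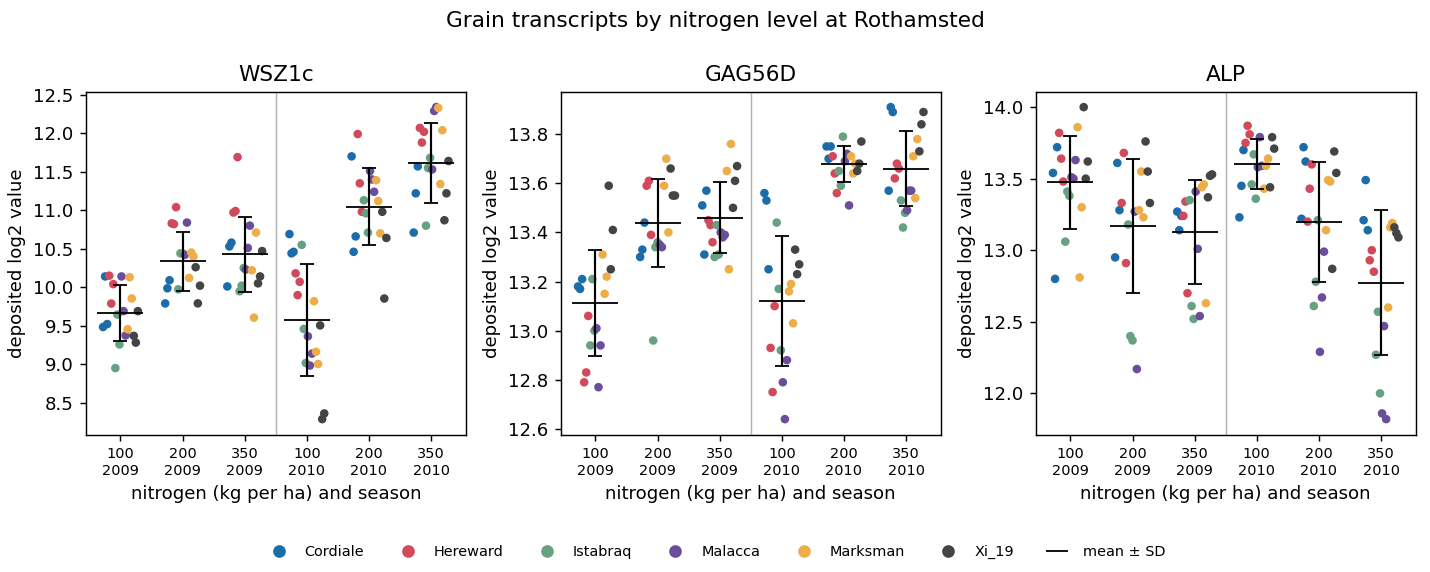
Log2 signal (vertical axis) of the serpin WSZ1c, the gamma gliadin GAG56D and the avenin-like protein ALP at Rothamsted against nitrogen supply (kg per ha, horizontal axis) in 2009 and 2010; each point is an array coloured by cultivar, and black marks give the mean and SD. The mean of WSZ1c went from 9.66 to 10.43 in 2009 and from 9.58 to 11.62 in 2010, while ALP fell by 0.35 and 0.83 on the log2 scale.

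Among the genes of chloroplast functions, PsbP, part of the oxygen-evolving complex of photosystem II, rose by 0.28 (SE 0.04, adjusted p = 1.09e-07), PRK, the phosphoribulokinase of the Calvin cycle, by 0.22 (SE 0.04) and Trx-M, a chloroplast thioredoxin, by 0.20 (SE 0.05). Falls were measured for 6-FEH, a fructan exohydrolase (-0.31, SE 0.05), the tubulins tubb2 (-0.19) and TUBA (-0.17), the ubiquitin-conjugating enzyme UBC1 (-0.13) and a pair of alpha-amylase and trypsin inhibitor genes, both labelled ATI (-0.14 and -0.12). Wx-A1, the granule-bound starch synthase that makes amylose, fell by 0.12 (adjusted p = 0.00236), a call lost without replicate 3 (adjusted p = 0.0931). Glu-D3, a low-molecular-weight glutenin subunit, did not pass (-0.05, SE 0.10, adjusted p = 0.758). Probe sets without a gene name reached 1.39 (SE 0.09) among the rises and -0.94 (SE 0.06) among the falls.

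By gene list, 5 of 5 alpha gliadin probe sets rose (5 when adjusted over the list alone), and the list as a whole moved up relative to other probe sets (camera adjusted p = 1.41e-07, and adjusted p = 0.00107 with an estimated correlation). Its members are gluten storage proteins. Gli-D2-16 rose by 0.10, from 14.86 to 14.96, close to the highest signal of 15.06, where a change can be compressed, and a probe set of Gli-D2-1 by 0.085. Gli-B2-11 (0.32, adjusted p = 2.25e-13) rose, and so did a second probe set of Gli-D2-1, with the suffix x_at of probe sets that can also bind related transcripts (0.78, SE 0.20, adjusted p = 0.00207, higher in 11 of 12 combinations). This mean came mainly from Malacca (3.99), with 0.04 to 0.21 in each other cultivar, and the call was lost without replicate 2 (adjusted p = 0.0508), without replicate 3 (0.162) and in 2009 alone (0.137). The probe sets given above for WSZ2a, GAG56D, avnla and Glu-D3, among others, share the suffix x_at. Of 31 photosynthesis probe sets, from only 3 genes and mostly from rbcl, the large subunit of Rubisco, and most with a mean under 6, 7 rose, 0 fell and 24 did not pass (limma; 8 rose when adjusted over the list alone). The camera adjusted p of this list was 0.000528, and the adjusted p = 0.0897 with an estimated correlation. Of 10 inhibitor probe sets 5 rose, all serpins, and 5 fell, the ATI genes and wci (5 and 5 when adjusted over the list alone), without a shift of the list (camera adjusted p = 0.0886). Of 5 defence probe sets, 0 rose and 3 fell, with THI1.3, a thionin, at -0.08 and LTP3, a lipid transfer protein, at -0.06 (0 and 3 when adjusted over the list alone; camera adjusted p = 0.0907), and both genes' calls were lost without replicate 2 (adjusted p = 0.488 and 0.259). Neither the 7 probe sets of late embryogenesis abundant (LEA) and ABA-related genes nor the 9 of histones held any that passed (0 and 0 when adjusted over the list alone), with camera adjusted p = 0.504 for both lists and LEA1 at 0.10 (adjusted p = 0.279).

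Across all 61178 probe sets limma called 14074 (23.0%) at an adjusted p under 0.05, 6547 higher and 7527 lower at N350, with a median absolute difference of 0.14 on the log2 scale. Of these, 100 differed by at least 1.5-fold, 72 higher and 28 lower, so the changes were many and small. The count was 4807 without replicate 3, and 8629 with probe sets of mean at least 6 alone, of which 28.3% were higher; with quantile normalization of all arrays the balance turned to 6278 higher and 6066 lower. Within seasons it was 1097 in 2009 (513 higher, 584 lower) and 12242 in 2010 (5358 higher, 6884 lower).

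From N100 to N200 the same serpins rose, WSZ1c by 1.08 (SE 0.08, adjusted p = 2.5e-22), WSZ2a by 0.84 (SE 0.08) and WSZ2b by 0.68. GAG56D rose by 0.44 and Gli-B2-11 by 0.32 (SE 0.03, adjusted p = 1.98e-12), and ALP fell by 0.37 and avnla by 0.24. EM and EMH2, LEA proteins of the maturing embryo, rose by 0.80 (SE 0.27, adjusted p = 0.0319) and 0.89 (SE 0.31, adjusted p = 0.0397). The spread of EM was unequal between groups. On the EM probe set plotted with Rab15 by site and season, Hereward plots at N100 in 2009 read 4.13, 11.49 and 10.89. At Rothamsted in 2011 the Hereward plots read 3.01, 3.35 and 3.06. The p-values of EM and EMH2 pool all groups, so they do not measure the spread between the N100 and N200 plots alone. In this comparison 9116 probe sets passed, 4025 higher and 5091 lower, and 51 by at least 1.5-fold. With probe sets of mean at least 6 alone, 1702 were higher and 4530 lower (27.3% higher), and with quantile normalization 3934 and 3830. The count was 689 in 2009 and 4818 in 2010, and it fell to 3119 without replicate 2, 4366 without replicate 3, 6009 without replicate 1, 5319 without Hereward, 4088 without Malacca and 5697 without Marksman.

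From N200 to N350 no named gene passed. WSZ1c differed by 0.33 (adjusted p = 0.0838), GAG56D by 0.004, and the alpha gliadin Gli-D2-16 by 0.008 (SE 0.02, adjusted p = 0.966). In all, 23 probe sets passed, 8 higher and 15 lower, none of them by 1.5-fold, while 3835 had an unadjusted p under 0.05. With limma on the arrays of these groups alone the count was 0, and it was 250 without replicate 1 and 0 without replicate 2 or replicate 3. Left-out cultivars also lowered it, to 3 without Cordiale or Marksman, 6 without Xi_19, 7 without Hereward and 11 without Malacca.

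The response of some serpins to nitrogen differed between seasons. WSZ1c rose from N100 to N350 by 0.77 (SE 0.11) in 2009 and by 2.04 (SE 0.11) in 2010, a difference of 1.28 (SE 0.15, adjusted p = 1.09e-08). Its means at N100, N200 and N350 were 9.66 ± 0.36, 10.34 ± 0.38 and 10.43 ± 0.49 in 2009 and 9.58 ± 0.73, 11.04 ± 0.50 and 11.62 ± 0.52 in 2010 (SD, n = 18 except 17 at N200 in 2009). WSZ2b rose by 0.55 and 1.22 (SE 0.09 each), a difference of 0.66 (adjusted p = 0.000709) that did not pass without replicate 2 (0.505) or replicate 3 (0.159), and the differences of the WSZ1b probe sets did not pass (0.19 and 0.14, adjusted p = 0.0699 and 0.103). wci, grouped with the inhibitors by its symbol, fell by 0.19 in 2009 and 0.84 in 2010 (SE 0.06 each), a difference of -0.66 (SE 0.09, adjusted p = 1.01e-07). The test of the difference called 422 probe sets, 185 with a more positive and 237 with a more negative change in 2010, 82 of them by at least 1.5-fold. This count was 91 with the arrays of N100 and N350 alone, where the balance turned to 62 more positive and 29 more negative. It was 992 with array weights, 760 with a block for the replicate number, 1840 without replicate 1, 36 without replicate 2, 38 without replicate 3, 281 without Cordiale, 268 without Istabraq and 118 without Marksman.

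The test of the nitrogen response between cultivars called 13 probe sets, 10 of them with a range of at least 1.5-fold. As many were called in 16 of 100 splits of the arrays, so chance could not be excluded. Malacca lay furthest from the other cultivars in a pair of named genes. WSZ2a rose by 2.33 in Malacca and by 0.65 to 1.13 in the others, a range of 1.68 (adjusted p = 0.00068), and the x_at probe set of Gli-D2-1 by 3.99 in Malacca against 0.04 to 0.21, a range of 3.94 (adjusted p = 0.000712). For Gli-D2-1 the test pooled the spread over cultivars, although its SD was 2.52 over all Malacca arrays and 0.131 over the others. Its p-value therefore does not measure the spread between Malacca plots. At N350 its Malacca plots read 4.70, 12.46 and 12.61 in 2009 and 7.19, 6.76 and 12.6 in 2010. The mean rise thus came mainly from some of the plots. ALP, on a second probe set, differed least in Cordiale (-0.09) and most in Malacca (-0.71), a range of 0.62 (adjusted p = 0.0297). On the ALP probe set given above for N350 against N100, the differences were -0.16 in Cordiale and -1.08 in Malacca. With the arrays of N100 and N350 alone none of the 3 passed (adjusted p = 0.202, 0.839 and 0.332) and the count was 1. It was 1012 without replicate 1, 0 without replicate 2 or replicate 3, 2 without Malacca, 3 without Xi_19 and 4 without Cordiale, and limma gave 0 in 2009 alone and 32 in 2010 alone. With both seasons, 3986 probe sets had an unadjusted p under 0.05.

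Cultivars were compared at N200 to find transcripts that mark each genotype. The storage proteins held the largest differences among named genes. Glu-D3 had a mean of 14.07 in Cordiale, 14.04 in Malacca and 14.06 in Marksman, and of 10.48 in Hereward and 10.11 in Xi_19. Against the other cultivars it was higher by 1.84, 1.80 and 1.82 in the first 3 and differed by -2.48 (SE 0.12, adjusted p = 4.98e-37) in Hereward and -2.92 (SE 0.12, adjusted p = 1.53e-43) in Xi_19. The x_at probe set of Gli-D2-1 had a mean of 7.68 in Malacca and 14.11 in the others, a difference of -6.42 (SE 0.25, adjusted p = 3.59e-46), which also put every other cultivar between 1.25 and 1.31 above its reference. WSZ2a was lower in Malacca by -2.92 (SE 0.10, 9.79 against 12.72, adjusted p = 6.56e-54). This also put Istabraq and Xi_19 above their references by 0.47 and 0.57, although their means of 12.62 and 12.70 were no higher than the 12.72 of the cultivars other than Malacca. Over the cultivars, the range of means was 3.97 for Glu-D3, 3.18 for WSZ2a and 6.44 for Gli-D2-1, with adjusted p = 3e-59, 1.07e-51 and 1.62e-43. Levels on 1 probe set depend on sequence as well as on abundance, and cultivar alleles were not analysed here. The probe sets of Glu-D3 and WSZ2a also carry the suffix x_at.

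**Figure D2:**
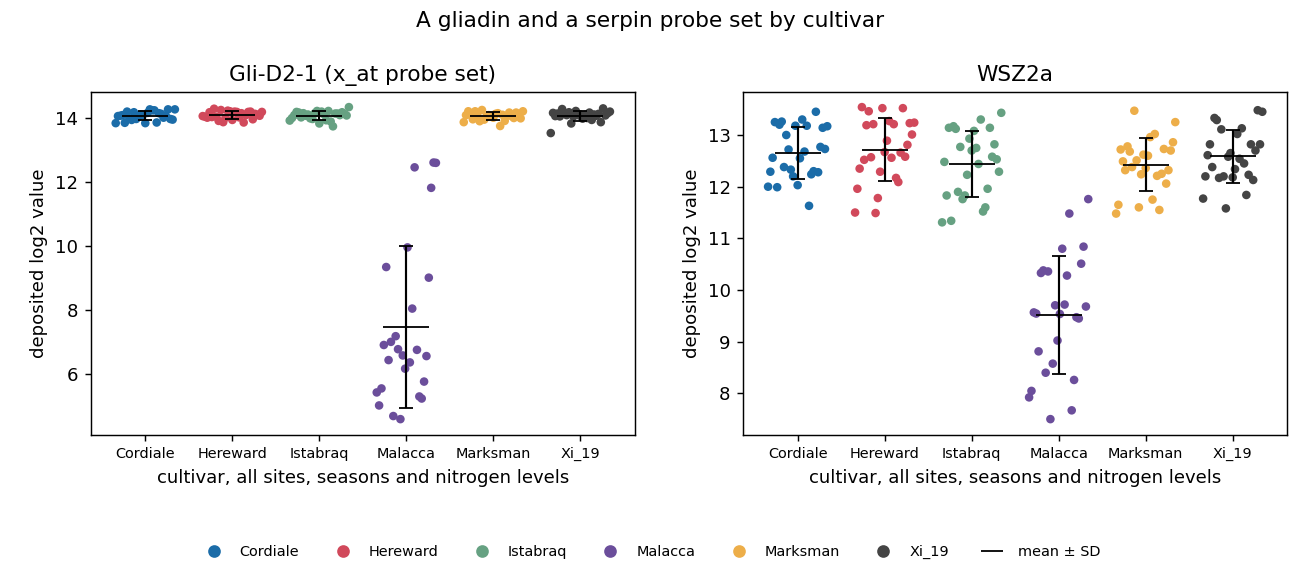
Log2 signal (vertical axis) of the alpha gliadin Gli-D2-1 (x_at probe set) and the serpin WSZ2a in each cultivar (horizontal axis) over all 161 arrays; each point is an array coloured by cultivar, and black marks give the mean and SD. Gli-D2-1 lay between 4.6 and 12.6 in the 26 Malacca arrays and at 13.5 or above in the 135 others.

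Other named genes differed between a cultivar and the mean of the others, a reference that a single other cultivar can move. Fructan exohydrolases, which degrade fructan reserves, differed in opposite directions: 6-FEH was higher in Istabraq (0.73, SE 0.06) and lower in Xi_19 (-0.98, SE 0.06, adjusted p = 5.96e-32), and 1-FEH was lower in Malacca (-0.63, SE 0.08). The histone gene wcH2B-8 was lower in Istabraq (-1.04) and Marksman (8.20 against 9.20, adjusted p = 1.51e-13). These low levels put Malacca 0.47 above its reference, at a level of 9.42 where Cordiale and Hereward had 9.50 and 9.60. The H2A gene wcH2A-9 was lower in Istabraq (-0.52, adjusted p = 0.0045, and 0.15 without replicate 2), with a mean of 10.08 against 10.12 in Xi_19. On another probe set it was higher in Marksman (0.76), where Hereward had the same mean of 11.01. In Xi_19 a probe set of rbcl was higher by 0.67 (SE 0.09) and hsp16.9A, a small heat shock protein, was lower (-1.39, SE 0.28, adjusted p = 3.27e-05). In Cordiale PER1 (-0.53), LEA1 (-0.35) and COMT1, a methyltransferase of lignin synthesis (-0.31), were lower. BMY1, a beta-amylase that degrades starch, was higher in Cordiale (0.86, adjusted p = 0.0223) and lower in Hereward (-0.90, adjusted p = 0.0144); without replicate 2 neither call held (0.237 and 0.115). Hereward had higher EMH2 (1.35, adjusted p = 0.00618) and EM (1.28, adjusted p = 0.0253), again not without replicate 2 (0.0798 and 0.163) and with similar means in Marksman (7.90 and 6.88 against 8.05 and 6.86). HGGT, an enzyme of tocotrienol synthesis, was lower in Hereward (-0.27). In Istabraq a second Glu-D3 probe set was lower than the mean of the others (-0.58), though not than Hereward or Xi_19 (11.82 against 11.33 and 11.24). In Malacca TBP1 was higher (0.30), with a mean of 10.20 where Cordiale had 10.24. Marksman had lower lgul, a lactoylglutathione lyase (-0.43), and GSTZ1, a glutathione transferase (-0.22). The largest difference of all belonged to a probe set without a gene name, which had a mean of 10.38 in Istabraq and 2.75, near the lowest signals, in the others. Another such probe set was lower in Xi_19 (-6.24, SE 0.27), a smaller fall than that of Gli-D2-1 in Malacca (-6.42).

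By list, 0 of 5 alpha gliadin probe sets rose and 3 fell in Malacca (0 and 3 when adjusted over the list alone), the only call of the lists fixed before that held under both settings among cultivars (camera adjusted p = 7.2e-06, and adjusted p = 0.00612 with an estimated correlation). The x_at probe set of Gli-D2-1 carried it, as the list had a mean of -1.35 and a median of -0.06. In Xi_19, 16 of 31 photosynthesis probe sets, mostly of rbcl, rose and 0 fell (18 and 0 when adjusted over the list alone), with camera adjusted p = 0.000162 and adjusted p = 0.0923 with an estimated correlation. The LEA list holds 4 genes, and most of its probe sets are those of EM and EMH2. In Hereward 5 of 7 LEA probe sets rose, 3 of 10 inhibitors and 3 of 9 histones, with 0 falling in each and 6, 3 and 3 risen when adjusted over the list alone. Their camera adjusted p values were 0.0158, 0.0107 and 0.0493, and the adjusted p = 0.566, 0.38 and 0.6 with an estimated correlation. In Marksman 5 of 7 LEA probe sets and 4 of 9 histones rose and 0 fell (5 and 4 when adjusted over the list alone), each with camera adjusted p = 0.0346 and adjusted p = 0.439 with an estimated correlation. In Istabraq 4 of 5 defence probe sets rose and 0 fell, and 0 of 31 photosynthesis probe sets rose and 5 fell (4 and 5 when adjusted over the list alone), both with camera adjusted p = 0.0436 and with adjusted p = 0.286 and 0.447 with an estimated correlation. In Malacca 1 of 10 inhibitors fell and 0 rose (2 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.0213, and adjusted p = 0.327 with an estimated correlation). No list fixed before passed in Cordiale, where camera gave adjusted p = 0.0717 both for the LEA genes, with 0 higher and 1 lower, and for defence proteins, with 0 higher and 2 lower. Adjusted over the list alone, these were 0 and 2, and 0 and 4. With lists assigned by name both passed there with camera (adjusted p = 0.0256 and 0.00243), but not with an estimated correlation (0.861 and 0.74).

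The test over all cultivars called 28432 probe sets (46.5%), 4511 of them with a range of at least 1.5-fold. Each cultivar against the others gave 10040 in Cordiale (5239 higher, 4801 lower), 10925 in Hereward (5879 and 5046), 9823 in Istabraq (5288 and 4535), 8093 in Malacca (4033 and 4060), 8802 in Marksman (4187 and 4615) and 16597 in Xi_19 (8567 and 8030). The balance of directions depended on the setting: in Xi_19 it turned with medians centred (6817 higher, 9145 lower) and with probe sets of mean at least 6 (4313 and 6012), and in Cordiale with array weights (8740 and 9758). Leaving out a replicate lowered these counts: the test over all cultivars to 18833 without replicate 3, Cordiale to 5282 without replicate 2 and 6177 without replicate 3, Hereward to 6696 and 7199, Istabraq to 6006 without replicate 3, Malacca to 4773 and Marksman to 4845 without replicate 2, and Xi_19 to 8985 without replicate 3.

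The seasons at Rothamsted were compared to see how far grain transcripts differ from year to year. The embryo genes EM and EMH2 differed most among named genes in each season contrast. All changes here are given relative to the median of all probe sets, which shifted by -0.15 from 2009 to 2010, by 0.155 from 2009 to 2011 and by 0.32 from 2010 to 2011 on the log2 scale. From 2009 to 2010 EM rose by 2.73 (SE 0.30), EMH2 by 2.34 (SE 0.26), Rab15, an ABA-responsive dehydrin, by 2.15 (SE 0.16) and WGA2, the germ agglutinin, by 1.38 (SE 0.20). In 2011 the same genes were far lower than in 2010, EM by -6.76 (SE 0.51, adjusted p = 1.83e-22), EMH2 by -5.92, WGA2 by -4.36 and Rab15 by -4.27 (SE 0.28, adjusted p = 1.52e-25), and lower than in 2009, EM by -4.15 (SE 0.52), EMH2 by -3.73, WGA2 by -3.15 and Rab15 by -2.22. The mean of EM in 2011 was 3.05, near the 1st percentile of 2.59, so the size of its differences against 2011 is limited by the lowest signals. BMY1 went the other way: it fell by 0.84 from 2009 to 2010 and rose in 2011 by 3.18 over 2009 (SE 0.34, adjusted p = 4.8e-16) and 3.75 over 2010. Before the median was subtracted, all of these differences had the same sign in 6 of 6 cultivars, which the rule for named genes required. The adjusted p values of single genes between seasons are also those of the differences before subtraction.

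Histone genes of dividing cells were higher in 2011, wcH2A-2 by 1.53 over 2009 (SE 0.15) and 1.43 over 2010, wcH2B-6 by 1.23 over 2009 and wcH2A-9 by 1.31 over 2010. PR5, a pathogenesis-related thaumatin-like protein, was higher in 2011 than in 2010 (2.25, SE 0.12), and WSZ1c was higher in 2011 than in 2009 (1.22, SE 0.11). A pair of gibberellin oxidase genes, GA20ox1d and GA20ox1a, and XTH, a xyloglucan endotransglucosylase of the cell wall, were lower in 2010 than in 2009 (-0.36, -0.36 and -0.34). A probe set without a gene name had a mean of 10.37 in 2011 and 2.91, near the lowest signals, in 2010.

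The LEA and ABA-related list followed these genes. It holds 4 genes, and most of its probe sets are those of EM and EMH2, so it largely restates them. From 2009 to 2010, 6 of its 7 probe sets rose and 1 fell (6 and 1 after centring, and 6 and 1 when adjusted over the list alone), with a median 1.72 above all probe sets, camera adjusted p = 0.000391 and adjusted p = 0.396 with an estimated correlation. From 2009 to 2011, 0 rose and 6 fell (0 and 6 after centring and when adjusted over the list alone), with a median of -2.61, camera adjusted p = 0.00699 and adjusted p = 0.689 with an estimated correlation. From 2010 to 2011, 1 rose and 6 fell (0 and 6 after centring, 1 and 6 when adjusted over the list alone), with a median of -4.27, camera adjusted p = 6.46e-07 and adjusted p = 0.0904 with an estimated correlation. The 9 histone probe sets, all of H2A genes, all rose from 2009 to 2011 (9 after centring and when adjusted over the list alone), with a median 0.82 above all probe sets, camera adjusted p = 0.0347 and adjusted p = 0.689 with an estimated correlation. They also all rose from 2010 to 2011, without a call for the list (camera adjusted p = 0.107). Photosynthesis, with the list fixed before, did not pass in any season contrast. From 2010 to 2011, 27 of its probe sets rose and 1 fell (26 and 4 after centring; camera adjusted p = 0.0675), from 2009 to 2011 22 and 4 (21 and 4; 0.099) and from 2009 to 2010 5 and 24 (10 and 9; 0.714). Alpha gliadins did not pass either, with camera adjusted p between 0.61 and 0.739, and their direction turned with centring: 3 rose and 0 fell from 2010 to 2011, against 0 and 3 after it. Inhibitors had camera adjusted p between 0.61 and 0.739, with 2 rising and 5 falling after centring from 2010 to 2011, and defence proteins between 0.714 and 0.943, with 2 and 2. With lists assigned by name, a choice made after the result was seen, 22 of 28 cell cycle and histone probe sets rose and 6 fell from 2009 to 2011 (camera adjusted p = 0.0497, and adjusted p = 0.482 with an estimated correlation). Photosynthesis then passed with camera from 2009 to 2011 and from 2010 to 2011 (adjusted p = 0.0397 and 0.0124), as did defence proteins (0.00119 and 0.000248), but none with an estimated correlation (0.353 and 0.221, and 0.353 and 0.17).

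**Figure D3:**
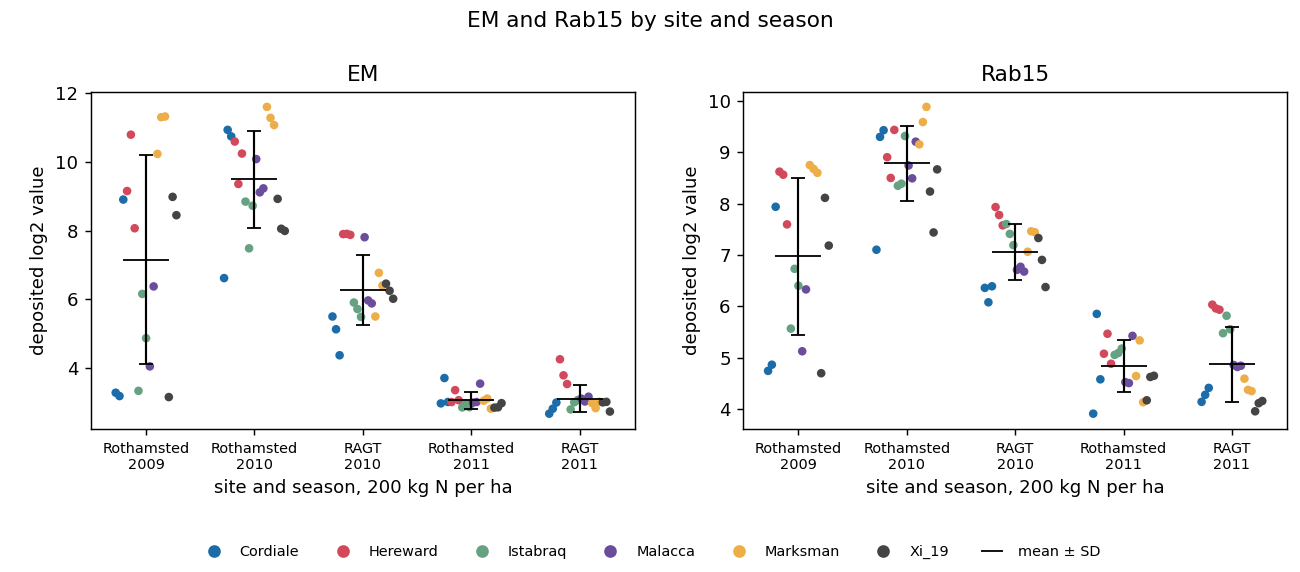
Log2 signal (vertical axis) of the LEA gene EM and the dehydrin gene Rab15 at N200 in each site and season (horizontal axis); each point is an array coloured by cultivar, and black marks give the mean and SD. The mean of EM was 9.49 at Rothamsted and 6.27 at RAGT in 2010, and 3.05 and 3.10 at the same sites in 2011.

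Before centring, 49747 probe sets differed between 2010 and 2009 (11073 higher, 38674 lower), 46281 between 2011 and 2009 (33000 higher, 13281 lower) and 52048 between 2011 and 2010 (43593 higher, 8455 lower). With the array medians centred the first gave 45494, 25333 higher and 20161 lower, the last gave 47193, 32217 higher and 14976 lower, and the second gave 46110, 32263 higher and 13847 lower. Quantile normalization of all arrays gave 44028 (21998 higher, 22030 lower), 41677 (21821 and 19856) and 42628 (22869 and 19759), in the order of the uncentred counts, so the balance of directions depended on the scaling. The deposited values of each season had their own distribution, with a 1st percentile of 2.33 ± 0.02 in 2009 (SD, n = 53), 2.15 ± 0.02 in 2010 (n = 72) and 2.59 ± 0.01 in 2011 (n = 36), so season and normalization cannot be told apart for these counts. The 3' minus 5' difference of the control transcripts, a measure of RNA quality, was -0.985 at Rothamsted in 2010 and -0.652 in 2011 at N200.

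RAGT was compared with Rothamsted within each season at N200. In 2010 the embryo genes were lower at RAGT: EM had a mean of 6.27 at RAGT and 9.49 at Rothamsted (-3.23, SE 0.51, adjusted p = 2.88e-07) and EMH2 differed by -3.04 (SE 0.44, adjusted p = 2.93e-08). The serpins WSZ1c (-0.62, SE 0.11, adjusted p = 3.34e-06) and WSZ2a (-0.58, SE 0.11, adjusted p = 1.02e-05) were lower too, and a probe set of rbcl with a low signal was higher (4.13 against 3.57, SE 0.11). Rab15 (-1.73, adjusted p = 5.68e-07), WGA2 (-1.55, adjusted p = 0.000163) and BMY1 (1.34, adjusted p = 0.00099) were chosen after their values were seen. In 2011 EM was near the lowest signals at both sites (3.10 and 3.05), so a difference in it could not be read. PR5 was lower at RAGT (-0.60, SE 0.12, adjusted p = 0.000223), hsp16.9A was higher (1.02, SE 0.33, adjusted p = 0.0454) and a probe set of rbcl was lower (-0.34, adjusted p = 0.0352). No named gene passed in both years with the same sign in 12 of 12 strata.

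By list, 0 of 7 LEA and ABA-related probe sets rose and 6 fell at RAGT in 2010 (0 and 6 when adjusted over the list alone), with a median of -2.85 (camera adjusted p = 3.92e-07, and adjusted p = 0.0404 with an estimated correlation). These probe sets come from 4 genes and are mostly those of EM and EMH2, so the list largely restates these genes. The photosynthesis list, mostly probe sets of rbcl, moved up, with 17 of 31 probe sets higher and 0 lower (18 and 0 when adjusted over the list alone, camera adjusted p = 9.9e-06, and adjusted p = 0.0404 with an estimated correlation). With lists assigned by name, neither call held with an estimated correlation (adjusted p = 0.0995 and 0.107). Alpha gliadins (0 higher, 1 lower; camera adjusted p = 0.13), inhibitors (3 and 5; 0.361), defence proteins (1 and 0; 0.361) and histones (0 and 0; 0.361) did not pass. In 2011, 0 photosynthesis probe sets rose and 2 fell (0 and 2 when adjusted over the list alone; camera adjusted p = 0.0473, and adjusted p = 0.732 with an estimated correlation), and the other 5 lists gave a camera adjusted p of 0.937.

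The site difference changed between years in a set of named genes. The change of PER1 was 0.61 (SE 0.10, adjusted p = 7.73e-07), that of a probe set of rbcl -0.73 (SE 0.12, adjusted p = 1.5e-06) and that of the tubulin tubb2 0.43 (SE 0.07, adjusted p = 2.4e-06). Over all probe sets 18644 differed between the sites in 2010 (9738 higher, 8906 lower; 7202 and 10222 with medians centred) and 3559 in 2011 (2549 higher, 1010 lower). The change between the years passed in 17998 (8796 more positive in 2011, 9202 more negative; 10480 and 6170 with medians centred). The 2010 count was 11638 without replicate 1 and 11108 without replicate 2. That of 2011 was 12202 with the arrays of that season alone, 2139 without replicate 1, 1069 without replicate 2, 1105 without replicate 3, 2055 without Cordiale, 1804 without Hereward and 2024 without Istabraq, and the test of the change gave 8836 without replicate 1, 9224 without replicate 2 and 11888 without Istabraq.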

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

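The tests for grain of another cultivar, for differences between plots shared with other plots and for RNA quality in the nitrogen response, and all 3 tests of the embryo genes, were chosen after the result was seen; the splits of the arrays, RNA quality in Malacca and the separate normalization of the seasons were set before.

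The test of the nitrogen response between cultivars called 13 probe sets, with ranges over cultivars of 1.68 for WSZ2a, 3.94 for Gli-D2-1 and 0.62 for the second probe set of ALP. Gli-D2-1 also varied within Malacca, from 4.6 to 12.6 over the 26 Malacca arrays (SD 2.52), against an SD of 0.131 over the 135 arrays of the other cultivars. Grain of another cultivar in some Malacca plots would raise other probe sets that Malacca lacks by the same share, but the highest slope of that share on the share by Gli-D2-1, over 5 possible donors, was 0.0546 (SE 0.0219, Marksman), where equal shares would give 1. RNA quality removed 0.0953% of the SD, which argues against it as the cause. A variant of this gliadin in Malacca that the probes read poorly, and a response to nitrogen or to the plot, may remain and were not tested, and chance could not be excluded for the 13 probe sets: 16 of 100 splits of the arrays gave as many, up to 787, a structure of the samples that may be the nitrogen effect itself, which these splits keep.

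Nitrogen changed transcripts more in 2010 than in 2009: the difference between seasons passed in 422 probe sets, with 1.28 for WSZ1c, -0.66 for wci and 0.66 for WSZ2b, and over 7840 probe sets the ratio of the nitrogen effects was 2.23 (r across probe sets 0.805). Separate normalization of the seasons would stretch cultivar differences as well, but their ratio over 16500 probe sets was 0.998, and with the control covariate for RNA quality the nitrogen ratio was still 2.17, so both are argued against as the whole cause. Differences between plots shared with other plots cannot be told apart from the nitrogen by season difference: the closest component of the spread between plots had r = 0.676 with it across probe sets in the 89 arrays of 2009 and 2011, within the 0.828 that chance combinations reach at their 95th percentile, and r = 0.2 in the 54 arrays outside the comparison. Of 100 splits, the real one included, 3 gave at least the real 422 probe sets, which argues against chance without excluding it. Up to 1542 were called in another split, a structure of the samples that may again be the nitrogen effect kept by the splits. A biological difference of the seasons in nitrogen uptake remains possible and was not tested.

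The site difference changed between 2010 and 2011 in 17998 probe sets, with 0.61 for PER1, -0.73 for rbcl and 0.43 for tubb2, and embryo genes were lower at RAGT in 2010, with a median of -2.85 over the LEA and ABA-related list. With the control covariate for RNA quality this median was -2.8, and after quantile normalization of all arrays it was -2.84, which argues against both as the cause. A difference in the share of embryo or in the stage of the grain at harvest may lie behind it. The first component of the spread between plots of a group held 37.4% of their variance over 89 arrays. On it, 6 of 6 list members, mostly probe sets of EM and EMH2, lay on the same side, which was taken as positive. The component had r = -0.622 with the site difference across probe sets (-0.612 without the list, with a chance 95th percentile of 0.333). Its r with the site difference of 2011 was 0.283. The 89 arrays, of 2009 and 2011, held none of 2010. However, this is a hypothesis formed from the site difference it was then tested on, and probe sets are not independent replicates. For the change of the site difference between years, 1 of 100 splits, the real one, gave 17998 probe sets, with 9330 in the highest other. This argues against chance for that count without excluding it. The splits mixed the sites within each year, which removes the site difference as well as its change. They did not test the hypothesis on the embryo or the stage.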

How the results depend on the processing

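Leaving out the arrays far from their group mean, and the lists assigned by name, were tests chosen after seeing the data; the other settings were set before. Of 2720 values of named genes under other settings, 2599 kept their direction and side of the threshold, 118 kept their direction but no longer passed, 3 came to pass and 0 reversed. Many of these genes were chosen as large called changes with the same sign in every stratum. That choice favours this tally, since leaving out a stratum could then hardly reverse them. The cause of changed counts was not tested, except that a fold minimum lowers a count by construction. Fewer probe sets or fewer arrays lowered some counts and raised others. With the arrays compared alone, the cultivars went from 28432 to 32414 and N350 against N100 from 14074 to 10695. With probe sets of mean at least 6, nitrogen by season went from 422 to 605 and N350 against N100 from 14074 to 8629.

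A block for the replicate number gave 49 for N350 against N200, 760 for the nitrogen by season difference and 24 for nitrogen by cultivar; mean correlations of same-numbered arrays ran from -0.00781 to 0.113, with a lowest of -0.587. Numbers held a shared structure in some environments: 40 of 53 arrays at Rothamsted in 2009 and 13 of 18 at RAGT in 2010 correlated best with their own number, against 5 of 18 at RAGT in 2011. The arrays compared alone gave 0, 91 and 1 for these, and 12202 for RAGT in 2011. For the 0, limma's main count at an unadjusted p under 0.05 was 3835.

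Probe sets with a mean of at least 6 gave 8629 for N350 against N100, 7 for nitrogen by cultivar, 17448 for the cultivars, 10325 for Xi_19, 17912, 19619 and 20451 for 2010 against 2009, 2011 against 2009 and 2011 against 2010, 11904 for RAGT in 2010 and 11089 for its change between years. Array weights gave 15773 for N200 against N100, 992 for nitrogen by season, 225 for nitrogen by cultivar, 18498 for Cordiale, 15132 for Istabraq, 13710 for Malacca and 13309 for RAGT in 2011. Without the arrays far from their group mean, nitrogen by cultivar gave 48.

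Changes of at least 1.5-fold numbered 100, 51 and 0 for N350 against N100, N200 against N100 and N350 against N200, 82 for nitrogen by season, 4511 for the cultivars, 931, 1181, 942, 906, 950 and 1211 for Cordiale, Hereward, Istabraq, Malacca, Marksman and Xi_19, 3038, 9338 and 13669 for the seasons in the order above, 923 and 112 for RAGT in 2010 and 2011 and 1660 for its change. In 2009 alone the counts were 1097 for N350 against N100, 689 for N200 against N100, 0 for N350 against N200 and 0 for nitrogen by cultivar, and in 2010 alone 4818, 66 and 32 for the last 3.

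Lists passed in 1 nitrogen test and 3 others with an estimated correlation, and in 29 others when assigned by name. With 1 probe set per gene only the inhibitors, with 7 genes, kept the minimum of 5 probe sets. That list passed in 1 nitrogen test and 2 others, and the other lists, alpha gliadins among them, could not be tested in this way. fry in 1 direction, which tests a list against no change and not against other probe sets, called 4 and 43, and between seasons these include shifts of whole arrays. Over all probe sets the variance share of cultivar at N200 was 6.06%, and at Rothamsted those of season and cultivar were 17.6% and 8.93%.

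With replicates, cultivars or environments left out in turn, the counts ranged from 4807 to 13727 for N350 against N100, 3119 to 10467 for N200 against N100, 0 to 250 for N350 against N200, 36 to 1840 for nitrogen by season, 0 to 1012 for nitrogen by cultivar and 18833 to 28290 for the cultivars. They ranged from 5282 to 11056 for Cordiale, 6696 to 11178 for Hereward, 6006 to 9186 for Istabraq, 4773 to 8762 for Malacca, 4845 to 8918 for Marksman and 8985 to 16751 for Xi_19. For RAGT they ranged from 11108 to 18790 in 2010, 1069 to 3934 in 2011 and 8836 to 19013 for the change, for nitrogen lists from 2 to 4. The residual share at N200 ranged from 12.2% to 16.0%, and at Rothamsted the nitrogen share from 2.35% to 3.62% and that of interactions from 22.1% to 25.8%. The season counts stayed within 1.5 times under each left-out replicate or cultivar, from 41739 to 51206. Signal over background limits differences against levels near the lowest signals, and 39.9% of probe sets had a mean of at least 6.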

Other observations

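The lists assigned by name to every named gene were written before expression was compared, but the choice to test them was made after the result was seen, whereas the splits of the arrays were set before.

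With these lists the avenin-like proteins, storage proteins rich in cysteine, form a group of 6 probe sets from 2 genes, ALP and avnla. From N100 to N350, 0 rose and 5 fell (0 and 6 when adjusted over the list alone), with a median of -0.37 (camera adjusted p = 9.89e-14, and adjusted p = 0.000221 with an estimated correlation). The group also set cultivars apart at N200: 6 of 6 fell in Istabraq (median -0.28, camera adjusted p = 4e-06, adjusted p = 0.0396 with an estimated correlation) and 5 of 6 rose in Xi_19 (median 0.40, camera adjusted p = 3.55e-06, adjusted p = 0.0237 with an estimated correlation). In Xi_19 the photosynthesis list, here 36 probe sets of 6 genes and mostly of rbcl, had 20 probe sets higher and 0 lower (camera adjusted p = 8.14e-07, adjusted p = 0.0212 with an estimated correlation). At RAGT in 2010 the calls of the LEA and photosynthesis lists did not hold under both settings, with camera adjusted p = 3.62e-10 and 0.000451 and adjusted p = 0.0995 and 0.107 with an estimated correlation.

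The 100 splits of the arrays within strata, each count including the real split, argue against chance for most comparisons without excluding it. In 1 of 100 splits, the real one, as many probe sets were called for N350 against N100 (14074, highest other 3759), N200 against N100 (9116, highest other 153) and the cultivars (28432, highest other 407). The same held for Cordiale (10040, highest other 97), Hereward (10925, 90), Istabraq (9823, 433), Malacca (8093, 861), Marksman (8802, 204) and Xi_19 (16597, 195). It also held for 2010 against 2009 (49747, highest other 31513), 2011 against 2009 (46281, 37354), 2011 against 2010 (52048, 32155), RAGT against Rothamsted in 2010 (18644, 16907) and in 2011 (3559, 4). For the seasons the separate distributions of the deposited values favour the real split, whatever the transcripts did. The splits exchange plots, so they do not test whether other years or other fields would differ in this way. For N350 against N200, 7 of 100 splits called at least the real 23 and the highest called 399, so chance could not be excluded, and a count several times the real one points to a structure of the samples, which may be the difference of N100 from the other levels, since the splits mix all 3.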
